A study of Homo sapiens with 6 samples.

How the data were processed

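Poly-adenylation selection and strand are not given in the sources used here; per the labels' protocols, RNA-seq libraries were made from 1 μg of total RNA of MDA-MB-231 cells with a TruSeq RNA sample preparation kit, in 3 untreated control samples and 3 samples irradiated with 20 Gy of X-rays and cultured for 24 h. The submitters' processing notes name HISAT2, StringTie and RSEM and the build hg38, without versions, roles or order. The authors deposited 1 table of TPM values, rounded to 2 decimals, with 61280 gene rows and 1 column per sample, and every column summed to the same total within rounding. TPM divides by transcript length and by the sample total, so a value is a share of the library: a rise of abundant transcripts lowers all others, and the read depth cannot be recovered. No between-sample scaling is recorded. Gene symbols were missing from 20671 rows, and 616 rows were loci assembled from the reads. Rows without a symbol held 1.94% to 2.48% of the TPM and stayed in the test. No row with a mean over 50 TPM was listed at 0 in any library, but 233 of the tested rows were, and such a 0 may be a failed estimate.

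Groups came from the sample titles. Replicates differed: at most 0.479% of the tested rows had identical values in any pair of libraries of a group, so all 6 were kept as separate samples. Genes with at least 1 TPM in at least 3 of the 6 samples were tested (14621 rows). Values were transformed to log2(TPM + 1), which understates the change of genes near 1 TPM, and all fold changes are on this scale. The irradiated and control groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, 4 residual and 3.39 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. SRM and the other polyamine enzymes were also compared by an exact permutation test over the 20 assignments of 6 values.

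A total of 30 gene lists with 619 distinct genes was fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. Every listed gene was found in the table by symbol or older symbol. The 27 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 27 lists; the correlation was also estimated from the data, and fry, which asks only whether a list's members move one way, was run as another alternative. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom rather than from the number of genes. That test has much less power, so a call lost in it need not come from correlated members. Beside each list, members past the threshold were counted with adjustment over all genes and with adjustment over the list alone. Named genes were the 10 largest rises and 10 largest falls among called genes with a symbol, at least 5 TPM in the higher group and no overlap between groups; in each list up to 4 called members with the largest changes, or, where none was called, the 2 most abundant; and SRM, ODC1, AMD1, SMS and SAT1. Some genes that met this rule are not reported here. PTPRC, ATF4, IFITM3, uncalled members named beside called ones and the tRNA synthetase genes fell outside the rule and were named after their values were seen.

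Gene types, transcript lengths, GC content and coordinates (1-based) were taken from GENCODE 29, which is on the same assembly as hg38, by gene identifier; 97.5% of tested rows matched. The replicate numbers are shared by both groups, but deviations of same-numbered samples from their group means had correlations of 0.03, -0.06 and -0.03, so the numbers were not treated as pairs and the blocked fit is an alternative only. The pipeline was tested on simulated TPM tables built from the control means and the observed residual spread, with 200 genes changed. In the step on 14611 genes, 8.33% of genes changed by 0.3, 26.5% of those changed by 0.5, 49.0% of those changed by 1 and 87.8% of those changed by 2 on the log2 scale of TPM were recovered, and 11 of 95 calls were false. A simulated shift of -0.25 in the DNA replication list was recovered with a median of -0.25 and no call among the other 26 lists. Noise was drawn independently for each gene, so this run could not show false list calls from correlated members. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-ratio scaling, quantile normalization, removal of mitochondrially encoded genes, eBayes without trend or with robust estimation, each library left out, and the replicate block. A fit on protein-coding genes alone was chosen after seeing the data, and so was a correction that removed cubic trends on GC content and log2 transcript length from each library, which covered 97.4% of tested genes.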

Results

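RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer line that carries mutant p53. The series compared cells that received 20 Gy of X-rays and were then cultured for 24 h with cells that were not treated, in 3 libraries per group. The labels give no culture time for the controls, so a difference in culture time cannot be separated from irradiation. The deposited table gave TPM (a transcript's share of its library, scaled to a fixed total) for each gene and library, so the number of reads behind each value is unknown and precision was judged from the spread between libraries. The labels number the replicates but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Between 14248 and 14417 genes reached 1 TPM in the control libraries, against 14592 to 14889 in the irradiated libraries. The 50 most abundant genes held 26.9% to 28.6% of the TPM in every library. Across the 14621 genes tested, Pearson correlations of log2(TPM + 1) were 0.980 to 0.988 within groups and 0.976 to 0.982 between groups. The first principal component, with 34.9% of the variance, separated the irradiated from the control libraries. On the second, with 21.8%, irradiated replicates 1, 2 and 3 lay at -23.9, 25.4 and -6.55, against -0.36 to 4.32 for the controls.

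Irradiation was followed by small changes in many transcripts. The fixed lists of DNA replication and S phase, ribosome biogenesis, integrated stress response, and hypoxia and glycolysis genes were lower against all other genes, and those of interferon-stimulated and antigen presentation genes were higher, by a camera test with a preset correlation. With the correlation estimated from these libraries, none of these 6 calls was kept (adjusted p = 0.118 to 0.404). That setting alone, of 19 alternatives, lost any of these 6. It rests on 4 residual degrees of freedom, so its power is low. The transcript of spermidine synthase, the enzyme named in the series title, did not pass the test except after a correction for GC content and transcript length. Of 14621 genes, 955 were higher and 595 lower at an adjusted p under 0.05 (limma on log2(TPM + 1), Benjamini-Hochberg), 10.6% of those tested. Only 65 of the 1550 called genes changed at least 2-fold, 38 upward and 27 downward. That number was 133 with a pseudocount of 0.1, 26 with no filter and 38 without control replicate 2. The median absolute log2 change of a called gene was 0.40. All 1550 had no overlap between the 3 irradiated and the 3 control values; 34.9% of all tested genes had none, where chance gives 10%. The balance of directions depended on the processing, with 809 higher and 785 lower calls after median-ratio scaling. It turned after a correction for GC content and transcript length, chosen after seeing the data, with 835 higher and 1446 lower calls. Leaving out 1 library moved the count from 1550 to 356 without control replicate 1, 306 without control replicate 2, 774 without control replicate 3, 688 without irradiated replicate 1, 1390 without irradiated replicate 2 and 488 without irradiated replicate 3, and no called gene changed direction in these fits.

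**Figure D1:**
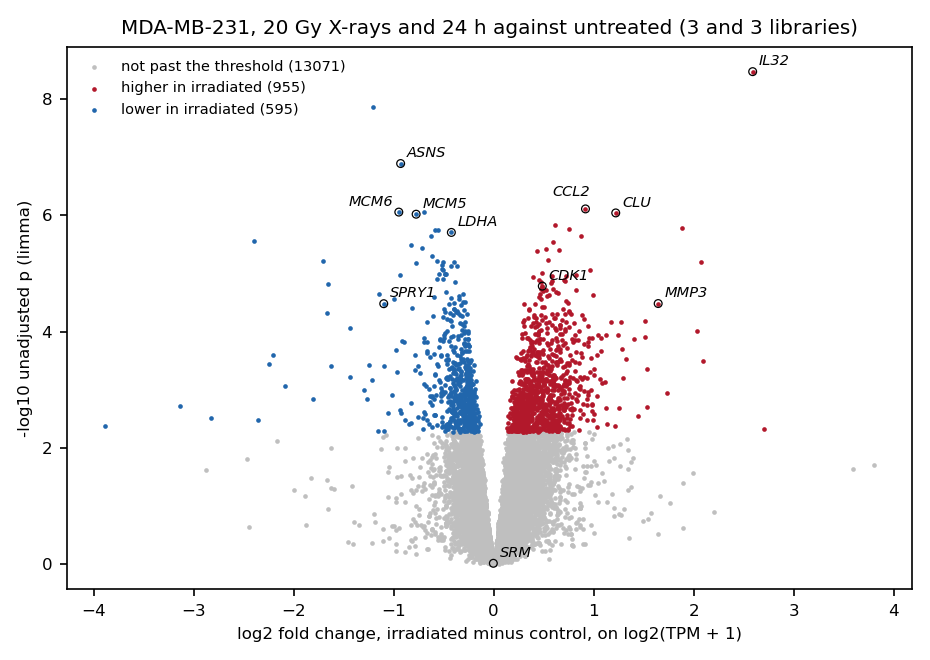
Log2 fold change on log2(TPM + 1) (x axis, irradiated minus control) against the unadjusted limma p on a -log10 scale (y axis) for the 14621 tested genes, each point 1 gene. The 955 genes higher and the 595 genes lower in irradiated cells are coloured, and SRM lies at the origin.

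IL32, a pro-inflammatory cytokine gene (ENSG00000008517; chromosome 16, 3065297 to 3082192, hg38), had the strongest evidence for a rise. It rose from 4.78 ± 0.275 to 33.9 ± 1.89 TPM (log2 change 2.59 ± 0.08 SE, adjusted p = 5.04e-05). Levels here and below are mean ± SD with n = 3 per group. MMP3, which encodes a matrix metalloproteinase, rose from 1.90 ± 0.653 to 7.94 ± 0.779 TPM (log2 change 1.65 ± 0.18 SE, adjusted p = 0.00552). CLU, the gene of the secreted chaperone clusterin, rose from 54.5 ± 2.72 to 129 ± 14.1 TPM (log2 change 1.22 ± 0.08 SE, adjusted p = 0.00177). Weakly expressed genes that rose were DOC2A, a calcium sensor of vesicle release (log2 change 1.07 ± 0.15, adjusted p = 0.00921), and ALOXE3, an epidermal lipoxygenase (log2 change 1.07 ± 0.16, adjusted p = 0.0114). Among the falls, SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling, went from 16.3 ± 1.65 to 7.12 ± 1.07 TPM (log2 change -1.10 ± 0.12 SE, adjusted p = 0.00552). DMC1, a recombinase of meiosis (log2 change -1.30 ± 0.25, adjusted p = 0.0226), and IMMP1L, a mitochondrial inner membrane peptidase subunit (log2 change -1.26 ± 0.26, adjusted p = 0.0263), also fell. Fits with 1 library left out have less power, so a call lost in them, here and below, need not depend on that library. ALOXE3 lost its call without control replicate 2 (adjusted p up to 0.0544). DMC1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 2 (adjusted p up to 0.0884), and with no filter. IMMP1L lost its call without control replicate 1 or 2 or irradiated replicate 1 or 2 (adjusted p up to 0.0940), and with no filter, eBayes without trend or robust eBayes.

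The other genes named for the size of their change were short or non-coding RNAs, or pseudogenes whose reads may be shared with near-identical copies. The small nucleolar RNA SNORA12 rose from 13.7 ± 3.34 to 60.7 ± 10.9 TPM (log2 change 2.07 ± 0.18 SE, adjusted p = 0.00309). BCYRN1, a short non-coding RNA known from neurons, fell from 270.4 ± 24.5 to 86.6 ± 22.7 TPM (log2 change -1.66 ± 0.17 SE, adjusted p = 0.00394); both passed in every alternative that tested them. U1 (2.70), SNORA23 (1.44), the antisense RNA MYO16-AS1 (1.06) and the pseudogene GTF2IP13 (1.01) were higher, with the log2 change in brackets. SNORA31B (-3.89), SNORA57 (-2.82), HMGN2P5 (-3.14), NCOR1P4 (-1.09) and the long non-coding RNA SNHG19 (-1.10) were lower. Tested genes with transcripts under 300 bases had a median residual SD of 0.80 on the log2 scale, against 0.17 for longer genes at the same level. For MYO16-AS1, no strand setting is given in the sources used here, so reads of the overlapping gene cannot be excluded. U1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 2 (adjusted p up to 0.146), after quantile normalization, and with a pseudocount of 0.1, no filter, eBayes without trend or robust eBayes. SNORA23 lost its call without control replicate 1 or 2 or irradiated replicate 1, 2 or 3 (adjusted p up to 0.0938), and with no filter, eBayes without trend or robust eBayes. MYO16-AS1 lost its call without control replicate 2 or 3 or irradiated replicate 1 (adjusted p up to 0.0688), and with no filter. GTF2IP13 lost its call without control replicate 2 or irradiated replicate 3 (adjusted p up to 0.0663), and with no filter. SNORA31B and SNORA57 lost their calls without control replicate 1, 2 or 3 or irradiated replicate 2 or 3 (adjusted p up to 0.121 and 0.126), and with a pseudocount of 0.1, no filter, eBayes without trend or robust eBayes. HMGN2P5 lost its call without control replicate 1, 2 or 3 or irradiated replicate 3 (adjusted p up to 0.102), and with a pseudocount of 0.1, no filter, eBayes without trend or robust eBayes. NCOR1P4 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 2 (adjusted p up to 0.135), and with a pseudocount of 0.1, no filter, eBayes without trend or robust eBayes. SNHG19 lost its call without control replicate 2 (adjusted p up to 0.0544), and with no filter.

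Genes of DNA replication and S phase were lower as a list (camera with a preset correlation, adjusted p = 6.80e-10), a call lost with an estimated correlation (adjusted p = 0.229). Of 35 tested members, 16 fell and none rose (22 fell and 1 rose when adjusted over the list alone), with a median log2 change of -0.23. All 6 genes of the MCM2 to MCM7 helicase were among them. MCM6 fell from 48.5 ± 1.12 to 24.7 ± 1.58 TPM (log2 change -0.95 ± 0.06 SE, adjusted p = 0.00177). MCM5 fell from 94.9 ± 3.10 to 55.1 ± 2.51 TPM (log2 change -0.77 ± 0.05 SE, adjusted p = 0.00177). MCM2 fell from 119 ± 3.52 to 80.05 ± 3.45 TPM (log2 change -0.56 ± 0.05 SE, adjusted p = 0.00309); these 3 passed under every alternative. CCNE2, which encodes cyclin E2, fell (log2 change -0.60 ± 0.11, adjusted p = 0.0207). CCNE2 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 (adjusted p up to 0.0862), and with no filter.

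Mitosis genes moved both ways: of 28 members, 4 rose and 7 fell (5 and 10 when adjusted over the list alone), and the list was not called (adjusted p = 0.0748). CDK1, the kinase that drives entry into mitosis, rose from 153 ± 4.45 to 215 ± 10.95 TPM (log2 change 0.49 ± 0.05 SE, adjusted p = 0.00419). CDC20, an activator of the anaphase-promoting complex, fell from 205 ± 3.54 to 153 ± 3.64 TPM (log2 change -0.43 ± 0.04 SE, adjusted p = 0.00328). KIF20A, a kinesin of cytokinesis, fell from 102 ± 1.15 to 71.3 ± 2.78 TPM (log2 change -0.51 ± 0.05 SE, adjusted p = 0.00324). HMMR, a spindle-associated protein gene, rose (log2 change 0.36 ± 0.08, adjusted p = 0.0402). Of the histone genes, whose near-identical copies make single values uncertain, H2BC5 rose (log2 change 0.62 ± 0.11, adjusted p = 0.0206) and H4C8 fell (log2 change -0.61 ± 0.13, adjusted p = 0.0289) among 11 tested; the same 1 and 1 passed when adjusted over the list alone, and the list was not called (adjusted p = 0.504). HMMR lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.126), and with no filter or eBayes without trend. H2BC5 lost its call without control replicate 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.0794), and with no filter. H4C8 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 2 (adjusted p up to 0.102), and with no filter.

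Of 26 p53 target genes, 2 rose and none fell, and none passed when adjusted over the list alone. These were TP53I3, an oxidoreductase gene (log2 change 0.33 ± 0.07, adjusted p = 0.0304), and CDKN1A, which encodes the cell cycle inhibitor p21 (log2 change 0.27 ± 0.07, adjusted p = 0.0482). The list median was 0.03 (adjusted p = 0.642), and -0.01 after quantile normalization. Of 24 homologous recombination and Fanconi genes, 3 rose and 1 fell (3 and 2 when adjusted over the list alone). FANCD2, central to crosslink repair, rose from 31.1 ± 2.13 to 42.9 ± 3.61 TPM (log2 change 0.45 ± 0.08 SE, adjusted p = 0.0191). EME1, a nuclease subunit gene, rose (log2 change 0.51 ± 0.11, adjusted p = 0.0313). RAD54L, a recombination motor gene, fell (log2 change -0.39 ± 0.09, adjusted p = 0.0330). Of 15 end joining genes, the polymerase genes POLL (log2 change 0.41 ± 0.08, adjusted p = 0.0231) and POLM (log2 change 0.37 ± 0.07, adjusted p = 0.0228) rose and XRCC6, which encodes Ku70, fell (log2 change -0.18 ± 0.03, adjusted p = 0.0191), with the same counts when adjusted over the list alone. Neither repair list was called (adjusted p = 0.707 and 0.642). Of 20 apoptosis regulators, BID rose (log2 change 0.36 ± 0.07, adjusted p = 0.0266) and BCL2L1 fell (log2 change -0.18 ± 0.04, adjusted p = 0.0290), the same 1 and 1 counts when adjusted over the list alone, with no call for the list (adjusted p = 0.504). TP53I3 lost its call without control replicate 1, 2 or 3 or irradiated replicate 3 (adjusted p up to 0.109), after median-ratio scaling or GC and length correction, and with no filter or eBayes without trend. CDKN1A lost its call with any 1 library left out (adjusted p up to 0.152), after median-ratio scaling, quantile normalization or GC and length correction, and with a pseudocount of 0.1, no filter or eBayes without trend. FANCD2 lost its call without control replicate 2 or 3 or irradiated replicate 3 (adjusted p up to 0.0788), and with no filter. EME1, RAD54L and XRCC6 lost their calls without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.0991, 0.122 and 0.0712), and with no filter or eBayes without trend. POLL lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.0856). POLM lost its call without control replicate 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.0899), after GC and length correction, and with no filter or eBayes without trend. BID lost its call without control replicate 1, 2 or 3 or irradiated replicate 3 (adjusted p up to 0.0913), after median-ratio scaling, and with no filter or eBayes without trend. BCL2L1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.109), after median-ratio scaling, and with no filter or eBayes without trend.

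Ribosome biogenesis genes were called lower as a list (adjusted p = 7.46e-11), but not with an estimated correlation (adjusted p = 0.224). Of 22 members, 12 fell and none rose (14 fell when adjusted over the list alone), with a median log2 change of -0.24. NPM1, the gene of the nucleolar chaperone nucleophosmin, fell from 3170.1 ± 146 to 2475 ± 101 TPM (log2 change -0.36 ± 0.05 SE, adjusted p = 0.00900) and passed under every alternative. NCL, the nucleolin gene, fell from 658 ± 40.6 to 499.7 ± 37.4 TPM (log2 change -0.40 ± 0.07 SE, adjusted p = 0.0161). NOLC1 fell (log2 change -0.36 ± 0.07, adjusted p = 0.0198) and RRS1 fell (log2 change -0.35 ± 0.07, adjusted p = 0.0279). Of 33 ribosomal protein genes, RPS2 (-0.24) and RPL5 (-0.16) fell, also when adjusted over the list alone, and the list was not called (median log2 change -0.00, adjusted p = 0.182) except after GC and length correction (-0.08, adjusted p = 0.00532). NCL lost its call without control replicate 1 or 2 (adjusted p up to 0.0676), and with no filter. NOLC1 lost its call without control replicate 1 or 2 (adjusted p up to 0.0785), and with no filter or eBayes without trend. RRS1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.104), and with no filter or eBayes without trend. RPS2 lost its call without control replicate 1 or 2 or irradiated replicate 3 (adjusted p up to 0.0700), after median-ratio scaling, and with no filter or eBayes without trend. RPL5 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.107), after median-ratio scaling, and with no filter or eBayes without trend.

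Genes of the integrated stress response, the programme through which the transcription factor ATF4 raises amino acid synthesis and transport, were lower as a list with the preset correlation (adjusted p = 8.05e-07), but not with an estimated one (adjusted p = 0.118). The estimated correlation of this list was -0.05, not above the preset 0.01, so correlation among members does not account for this loss. With an estimated correlation, camera also takes its p from the 4 residual degrees of freedom, which lowers its power. Of 19 members, 9 fell and none rose, the same count when adjusted over the list alone, with a median log2 change of -0.20. ASNS, which makes asparagine (ENSG00000070669; chromosome 7, 97852118 to 97872542), fell from 86.0 ± 2.90 to 44.7 ± 0.847 TPM (log2 change -0.93 ± 0.05 SE, adjusted p = 0.000636). DDIT4, an inhibitor of mTORC1, fell from 35.9 ± 1.34 to 20.6 ± 1.34 TPM (log2 change -0.77 ± 0.07 SE, adjusted p = 0.00313). SLC7A5, the light chain of a large neutral amino acid transporter, fell from 71.7 ± 1.72 to 46.3 ± 1.19 TPM (log2 change -0.62 ± 0.05 SE, adjusted p = 0.00211). PSAT1, of serine synthesis, fell from 98.7 ± 3.68 to 70.0 ± 1.10 TPM (log2 change -0.49 ± 0.05 SE, adjusted p = 0.00358). All 4 passed under every alternative. The stress genes DDIT3, ATF3, TRIB3 and CHAC1 of the same list did not pass (log2 changes 0.08, 0.33, -0.09 and -0.02, adjusted p = 0.186 or more). Of 18 endoplasmic reticulum chaperone genes, PDIA3 alone passed (log2 change -0.16 ± 0.04, adjusted p = 0.0456), and none did when adjusted over the list alone (list adjusted p = 0.165). PDIA3 lost its call with any 1 library left out (adjusted p up to 0.147), after median-ratio scaling or quantile normalization, and with no filter, mitochondrially encoded genes removed or eBayes without trend.

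**Figure D2:**
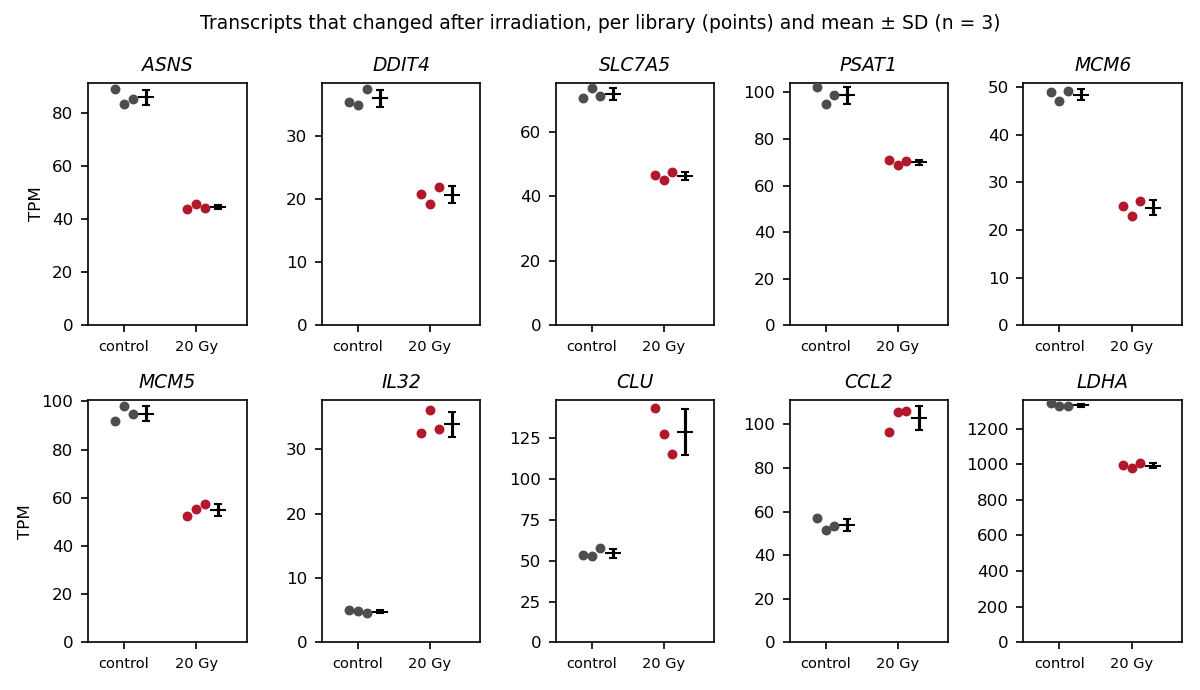
TPM (y axis, from 0) of 10 transcripts in the 3 control and the 3 irradiated libraries, points for libraries and bars for mean ± SD. In each panel the 2 groups do not overlap, with ASNS at 86.0 ± 2.90 and 44.7 ± 0.847 TPM.

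Hypoxia and glycolysis genes were lower as a list (median log2 change -0.19, adjusted p = 0.000202), a call lost with an estimated correlation (adjusted p = 0.216). The estimated correlation of this list was 0.02, near the preset 0.01, so correlation among members alone does not account for this loss. The median was -0.12 without irradiated replicate 2 and -0.26 after GC and length correction. Of 19 members, 4 fell and none rose (5 fell when adjusted over the list alone). LDHA, the lactate dehydrogenase A gene, fell from 1329.6 ± 9.44 to 992 ± 14.3 TPM (log2 change -0.42 ± 0.03 SE, adjusted p = 0.00208) and passed under every alternative. BNIP3, a mitophagy receptor gene, fell (log2 change -0.41 ± 0.07, adjusted p = 0.0151). The glycolytic genes ENO1 (log2 change -0.22 ± 0.04, adjusted p = 0.0205) and GAPDH (log2 change -0.19 ± 0.04, adjusted p = 0.0366) also fell, while HK2, PFKFB3, ALDOA and PGK1 did not pass (adjusted p = 0.128 or more). GAPDH and LDHA have many processed pseudogenes, so part of their reads may be assigned elsewhere. Of 18 NRF2 antioxidant genes, PRDX1 rose (log2 change 0.17 ± 0.04, adjusted p = 0.0490) and GCLM fell (log2 change -0.41 ± 0.09, adjusted p = 0.0321) (1 rose and 3 fell when adjusted over the list alone; list adjusted p = 0.870). Of 13 mitochondrially encoded genes, MT-CO2 alone passed, rising from 8048 ± 508 to 10290.2 ± 468 TPM (log2 change 0.36 ± 0.06 SE, adjusted p = 0.0149), also when adjusted over the list alone, and the list was not called (adjusted p = 0.182). BNIP3 lost its call without control replicate 1 or 2 or irradiated replicate 3 (adjusted p up to 0.0671), and with no filter. ENO1 lost its call without control replicate 1 or 2 or irradiated replicate 1 or 3 (adjusted p up to 0.0700), after median-ratio scaling, and with no filter or eBayes without trend. GAPDH lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.106), after median-ratio scaling, and with no filter or eBayes without trend. PRDX1 lost its call without control replicate 1 or 2 or irradiated replicate 1, 2 or 3 (adjusted p up to 0.154), after median-ratio scaling or GC and length correction, and with no filter or eBayes without trend. GCLM lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.113), and with no filter or eBayes without trend. MT-CO2 lost its call without control replicate 2 (adjusted p up to 0.0626), after median-ratio scaling, and with no filter.

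Interferon-stimulated genes were higher as a list with the preset correlation (adjusted p = 0.000721), but not with an estimated one (adjusted p = 0.404). Of 32 members, 7 rose and 1 fell (12 and 1 when adjusted over the list alone), with a median log2 change of 0.20. OAS1, a sensor of double-stranded RNA, rose from 9.88 ± 0.547 to 16.2 ± 1.03 TPM (log2 change 0.66 ± 0.08 SE, adjusted p = 0.00740) and passed under every alternative. IFI6 rose from 48.5 ± 6.80 to 75.0 ± 4.76 TPM (log2 change 0.62 ± 0.10 SE, adjusted p = 0.0140). SAMD9L rose (log2 change 0.72 ± 0.13, adjusted p = 0.0189) and IFI44L, at low level, rose from 0.737 ± 0.142 to 1.71 ± 0.0850 TPM (log2 change 0.64 ± 0.14 SE, adjusted p = 0.0313). Antigen presentation genes rose in 7 of 15 cases (10 when adjusted over the list alone) and none fell, with a median log2 change of 0.24, or 0.12 after GC and length correction. PSMB9, an immunoproteasome subunit gene, rose from 27.0 ± 2.77 to 46.1 ± 3.36 TPM (log2 change 0.75 ± 0.09 SE, adjusted p = 0.00640). HLA-C, a class I gene whose reads may be shared with other class I genes, rose from 200.6 ± 1.18 to 256 ± 9.84 TPM (log2 change 0.35 ± 0.04 SE, adjusted p = 0.00617); both passed under every alternative. TAPBP (log2 change 0.36 ± 0.07, adjusted p = 0.0259) and PSMB8 (log2 change 0.35 ± 0.07, adjusted p = 0.0271) also rose. The antigen presentation list was also called (adjusted p = 0.000240) and lost with an estimated correlation (adjusted p = 0.224). All 3 leukocyte markers above the expression filter rose, also when adjusted over the list alone. CD68, a lysosomal protein gene, rose from 63.2 ± 4.02 to 94.7 ± 2.62 TPM (log2 change 0.58 ± 0.06 SE, adjusted p = 0.00391). LCP1 rose (log2 change 0.22 ± 0.05, adjusted p = 0.0377) and CD3D rose from 0.523 ± 0.415 to 2.06 ± 0.118 TPM (log2 change 1.04 ± 0.21 SE, adjusted p = 0.0248). The other 12 of 15 leukocyte markers were below the filter, and PTPRC was at 40.4 TPM in irradiated replicate 1 and at most 0.45 TPM in every other library. IFI6 lost its call without control replicate 1 or 2 or irradiated replicate 3 (adjusted p up to 0.0584), and with no filter. SAMD9L lost its call without control replicate 1, 2 or 3 or irradiated replicate 3 (adjusted p up to 0.0712), and with no filter. IFI44L lost its call with any 1 library left out (adjusted p up to 0.107), after quantile normalization, and with no filter. TAPBP lost its call with any 1 library left out (adjusted p up to 0.0718), after GC and length correction, and with no filter or eBayes without trend. PSMB8 lost its call without control replicate 1 or 2 or irradiated replicate 1, 2 or 3 (adjusted p up to 0.0961), after median-ratio scaling or GC and length correction, and with no filter or eBayes without trend. LCP1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.124), and with no filter or eBayes without trend. CD3D lost its call without control replicate 1 or 3 or irradiated replicate 1, 2 or 3 (adjusted p up to 0.0852), and with no filter.

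Among secreted signals, CCL2, a monocyte chemoattractant gene, rose from 53.9 ± 2.88 to 103 ± 5.42 TPM (log2 change 0.92 ± 0.06 SE, adjusted p = 0.00177) and passed under every alternative. Of the 8 genes of the fixed cytokine and chemokine list above the filter, only CCL2 passed, also when adjusted over the list alone (list adjusted p = 0.404). IL32, which rose as above, is not on that list. The pro-fibrotic factor list was fixed because the series title names muscle fibrosis, but these are cultured breast cancer cells and no fibrosis was measured. Of 17 tested pro-fibrotic members, 4 rose and none fell (6 rose when adjusted over the list alone). The list was not called against other genes (camera, adjusted p = 0.0953). By fry, which does not make that comparison, it was higher (adjusted p = 0.0258). EDN1, the endothelin-1 gene, rose from 11.7 ± 0.263 to 18.7 ± 0.425 TPM (log2 change 0.64 ± 0.07 SE, adjusted p = 0.00479). TGFB1, the gene of transforming growth factor beta 1, rose from 34.0 ± 1.36 to 45.8 ± 0.155 TPM (log2 change 0.42 ± 0.05 SE, adjusted p = 0.00705). TGFBI, a matrix protein gene induced by that factor, rose from 58.3 ± 0.268 to 81.2 ± 5.09 TPM (log2 change 0.47 ± 0.06 SE, adjusted p = 0.00640). CCN1 rose (log2 change 0.17 ± 0.04, adjusted p = 0.0377). Of 23 extracellular matrix genes, 5 rose and 1 fell (8 and 2 when adjusted over the list alone; list adjusted p = 0.165), among them MMP3 as above, SPARC (log2 change 0.39 ± 0.09, adjusted p = 0.0375), MMP14 (log2 change 0.36 ± 0.05, adjusted p = 0.0111) and, lower, the fibronectin gene FN1 (log2 change -0.37 ± 0.08, adjusted p = 0.0269). EDN1, TGFB1, TGFBI and MMP3 passed under every alternative. CCN1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.118), after median-ratio scaling, quantile normalization or GC and length correction, and with no filter or eBayes without trend. SPARC lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.104), and with no filter or eBayes without trend. MMP14 lost its call without control replicate 1 (adjusted p up to 0.0516). FN1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.104), after GC and length correction, and with no filter or eBayes without trend.

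Of 17 NF-kB response genes, 3 rose and 3 fell, with the same counts when adjusted over the list alone (list adjusted p = 0.731). NFKB2 rose (log2 change 0.58 ± 0.06, adjusted p = 0.00375) and passed under every alternative, and TRAF1 rose (log2 change 0.75 ± 0.14, adjusted p = 0.0198). BCL3 fell (log2 change -0.67 ± 0.16, adjusted p = 0.0391) and IER3 fell (log2 change -0.32 ± 0.06, adjusted p = 0.0186). Of 20 immediate early genes, 2 rose and 5 fell, again with the same counts when adjusted over the list alone (list adjusted p = 0.343). DUSP1, a phosphatase of MAP kinases, rose (log2 change 0.45 ± 0.06, adjusted p = 0.00718). PHLDA1 (log2 change -0.62 ± 0.05, adjusted p = 0.00309), SPRY4 (log2 change -0.48 ± 0.09, adjusted p = 0.0231) and DUSP5 (log2 change -0.35 ± 0.06, adjusted p = 0.0142) fell. DUSP1 and PHLDA1 passed under every alternative. TRAF1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 3 (adjusted p up to 0.0740), and with no filter. BCL3 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.123), and with no filter or eBayes without trend. IER3 lost its call without control replicate 1 or irradiated replicate 3 (adjusted p up to 0.0620), and with no filter or eBayes without trend. SPRY4 lost its call without control replicate 1, 2 or 3 (adjusted p up to 0.0895), and with no filter. DUSP5 lost its call without control replicate 1 or 2 (adjusted p up to 0.0555).

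Lysosome genes rose in 4 of 23 cases and none fell, the same when adjusted over the list alone. NEU1, the lysosomal sialidase gene, rose (log2 change 0.62 ± 0.07, adjusted p = 0.00466) and passed under every alternative. GLB1, which encodes lysosomal beta-galactosidase, rose (log2 change 0.22 ± 0.04, adjusted p = 0.0261). HEXA rose (log2 change 0.23 ± 0.06, adjusted p = 0.0480). The list was called (median log2 change 0.09, adjusted p = 0.0239) but not with an estimated correlation (adjusted p = 0.490), after median-ratio scaling, after GC and length correction (median 0.02, adjusted p = 0.367) or without control replicate 1. Of 22 cholesterol synthesis genes, 3 rose and 1 fell (6 and 2 when adjusted over the list alone; list adjusted p = 0.504): MSMO1 (0.27), NSDHL (0.22) and FDPS (0.19) were higher and SREBF2 (-0.26) lower. GLB1 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.104), and with eBayes without trend. HEXA and FDPS lost their calls with any 1 library left out (adjusted p up to 0.152 and 0.140), after median-ratio scaling or GC and length correction, and with a pseudocount of 0.1, no filter or eBayes without trend. MSMO1 lost its call without control replicate 2 or irradiated replicate 3 (adjusted p up to 0.0624). NSDHL lost its call with any 1 library left out (adjusted p up to 0.151), after median-ratio scaling, quantile normalization or GC and length correction, and with no filter or eBayes without trend. SREBF2 lost its call with any 1 library left out (adjusted p up to 0.0948), and with no filter or eBayes without trend.

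Mesenchymal genes rose in 1 and fell in 4 of 16 cases (2 and 6 when adjusted over the list alone; list adjusted p = 0.248). The falls included AXL, a receptor tyrosine kinase gene (log2 change -0.36 ± 0.05, adjusted p = 0.00921), which passed under every alternative, and S100A4 (log2 change -0.83 ± 0.20, adjusted p = 0.0422). Epithelial genes rose in 3 of 11 cases and none fell, the same when adjusted over the list alone (list adjusted p = 0.642): MUC1 (log2 change 0.61 ± 0.13, adjusted p = 0.0287), CLDN7 (log2 change 0.38 ± 0.09, adjusted p = 0.0460) and KRT7 (log2 change 0.25 ± 0.04, adjusted p = 0.0167). Of 9 tested luminal breast markers none passed by either adjustment, with KRT8 at 427 ± 12.03 and 459.8 ± 21.4 TPM and KRT18 at 364 ± 11.4 and 352 ± 16.1 TPM in control and irradiated cells (list adjusted p = 0.931). Of 12 fibroblast markers, 4 exceeded the filter and none passed (2 were higher when adjusted over the list alone), with COL1A1 at 8.70 ± 1.74 and 11.5 ± 2.19 TPM and PDGFRB at 2.64 ± 0.255 and 4.12 ± 0.839 TPM. Of 16 skeletal muscle markers, MYH3 (1.26 ± 0.374 and 2.79 ± 0.775 TPM) and DES (0.860 ± 0.262 and 1.34 ± 0.270 TPM) exceeded the filter and neither passed over all genes, except MYH3 after GC and length correction (adjusted p = 0.0433); 1 was higher when adjusted over the list alone. S100A4 lost its call without control replicate 1, 2 or 3 or irradiated replicate 1 or 3 (adjusted p up to 0.110), after quantile normalization, and with no filter or eBayes without trend. MUC1 lost its call with any 1 library left out (adjusted p up to 0.0887), and with no filter. CLDN7 lost its call with any 1 library left out (adjusted p up to 0.143), after median-ratio scaling, quantile normalization or GC and length correction, and with no filter or eBayes without trend. KRT7 lost its call without control replicate 1 or 2 (adjusted p up to 0.0722), after median-ratio scaling or GC and length correction, and with no filter or eBayes without trend.

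**Figure D3:**
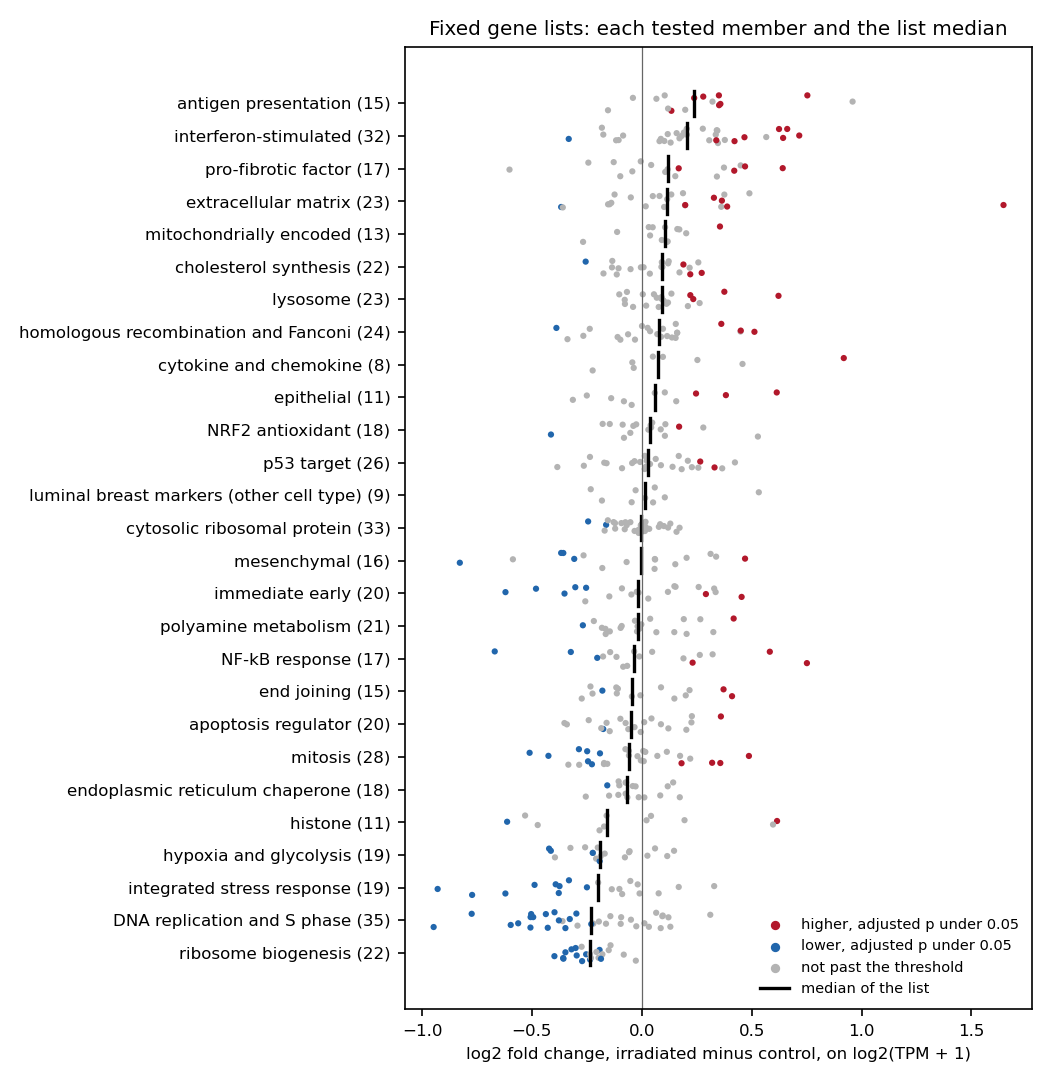
Log2 fold change on log2(TPM + 1) (x axis, irradiated minus control) of each tested member of 27 fixed gene lists (y axis, number tested in brackets), with black bars for list medians. Medians run from -0.24 for ribosome biogenesis to 0.24 for antigen presentation, and coloured points passed an adjusted p under 0.05.

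The comparison also asked whether irradiation changes transcripts of polyamine metabolism, since the series title names spermidine synthase. SRM, the gene of that enzyme (ENSG00000116649; chromosome 1, 11054584 to 11060024, hg38), was at 123 ± 3.27 and 123 ± 1.21 TPM in control and irradiated cells, with individual values that overlapped. Its log2 change was -0.00 with a 95% interval of -0.10 to 0.09, which allows a ratio of 0.935 to 1.07 (adjusted p = 0.978; exact two-sided permutation p = 1, where 3 against 3 cannot go below 0.1). After the correction for GC content and length, SRM was lower (log2 change -0.16, adjusted p = 0.0339). ODC1, the rate-limiting enzyme of putrescine synthesis, was at 165 ± 6.72 and 154 ± 4.17 TPM, and AMD1, which supplies decarboxylated S-adenosylmethionine, at 73.3 ± 4.90 and 72.4 ± 5.60 TPM; neither passed (adjusted p = 0.219 and 0.892). SMS, the spermine synthase gene, fell from 206 ± 5.55 to 171 ± 8.99 TPM (log2 change -0.27 ± 0.05 SE, adjusted p = 0.0205). SAT1, which acetylates spermidine and spermine, was at 75.8 ± 3.26 and 86.8 ± 6.12 TPM and did not pass (adjusted p = 0.0997). Of 21 polyamine metabolism genes, AZIN2 rose (log2 change 0.42 ± 0.11, adjusted p = 0.0485) and SMS fell (none rose and 1 fell when adjusted over the list alone), and the list was not called (median log2 change -0.02, adjusted p = 0.504). After GC and length correction the list was still not called, but its median was -0.14 (adjusted p = 0.154), and ODC1 was at -0.16 (adjusted p = 0.0501). SMS lost its call without control replicate 1 or 2 (adjusted p up to 0.0856), and with no filter or eBayes without trend. AZIN2 lost its call with any 1 library left out (adjusted p up to 0.152), after quantile normalization, and with no filter or eBayes without trend.

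**Figure D4:**
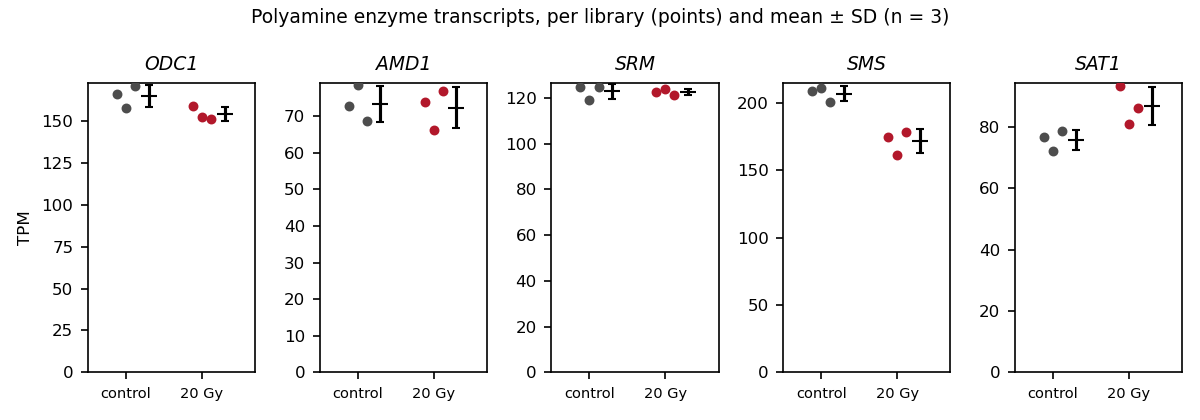
TPM (y axis, from 0) of 5 polyamine enzyme transcripts in the 3 control and the 3 irradiated libraries, points for libraries and bars for mean ± SD. SRM was at 123 ± 3.27 and 123 ± 1.21 TPM in control and irradiated cells.

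In all, 7 of 27 lists passed the camera test with the preset correlation, 3 higher and 4 lower, and none of them passed with the correlation estimated from these libraries. Fry, which does not compare with other genes, called all 7 (adjusted p = 0.0107 or lower). Estimated correlations ran from -0.05 (integrated stress response) to 0.23 (ribosome biogenesis). For integrated stress response and for hypoxia and glycolysis (0.02), correlation alone does not account for the loss. The estimated setting also takes its p from 4 residual degrees of freedom, so for all 7 lists a lost call may reflect low power. A different split of the 6 libraries into 3 and 3 also called 7 lists, and the remaining ones 1 to 5. These splits mix irradiated with control libraries and keep part of the real difference, so their counts are not a chance rate. The list median, list mean and camera direction differed in sign for the end joining, NF-kB response, polyamine, NRF2 and luminal lists, none of which was called.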

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

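The fits on protein-coding genes alone and with GC content and length corrected were chosen after seeing the data. The alternatives kept the direction of the 1550 called genes that they tested, except IFITM3 after GC and length correction (0.14 to -0.0019, a gene named after its values were seen), but not their number. The count was 1457 with a pseudocount of 0.1, 1551 with a filter of 5 TPM, 1594 with median-ratio scaling, 1628 with quantile normalization, 1651 without mitochondrially encoded genes and 1623 with robust eBayes. It fell to 993 with eBayes without trend and to 497 with no filter, where 32164 genes share the adjustment. The share of calls that were higher was 61.6% as reported, 50.8% with median-ratio scaling, 72.4% without trend, 51.2% without irradiated replicate 3 and 36.6% after GC and length correction, where most calls were lower; no scaling moved the median of all genes by as much as 0.1. With 1 library left out the count ranged from 306 (without control replicate 2) to 1390 (without irradiated replicate 2). With the replicate block it was 362, of which 355 were among the 1550; same-numbered samples had correlations of deviations of 0.03, -0.06 and -0.03, and not every sample correlated best with its own number, so a lost call under the block is not read as a weaker effect. On protein-coding genes alone it was 1794, and after GC and length correction 2281. Genes changed at least 2-fold numbered 133 with a pseudocount of 0.1, 26 with no filter, 29 with a filter of 5 TPM, 35 on protein-coding genes alone and 38 to 63 with 1 library left out (38 without control replicate 2, 40 without control replicate 1), against 65. Lists called numbered 11 with no filter, 0 with the correlation estimated and 6 to 8 otherwise (8 with fry, the pro-fibrotic list among them), against 7. Of 101 called named genes, 33 passed under every setting that tested them. With the replicate block 52 lost their calls, and the lost calls given for single genes above leave this setting out. SRM passed the threshold after GC and length correction, with a log2 change of -0.16 (adjusted p = 0.0339), and had an adjusted p of at least 0.793 in every other fit. Its log2 change turned to 0.017 with quantile normalization, 0.0083 without mitochondrially encoded genes, 0.00018 on protein-coding genes alone, and ranged from -0.024 to 0.0088 with 1 library left out. Uncalled values near 0 also changed sign. With no filter the medians of the cytokine, apoptosis and mesenchymal lists became -0.0034, 0.0027 and 0.058. With a filter of 5 TPM the epithelial and luminal medians became -0.046 and -0.028. The luminal median was -0.0032 with median-ratio scaling and -0.024 with quantile normalization, which also turned the p53 list to -0.011. Without mitochondrially encoded genes the mesenchymal and ribosomal protein medians were 0.0035 and 0.0060. After GC and length correction the NRF2, epithelial and luminal medians were -0.037, -0.097 and -0.064, and the gene AMD1 was at 0.0041. The polyamine median moved to -0.14 there, the ribosomal protein median to -0.083 and the cytokine, matrix, cholesterol and lysosome medians to 0.0043, 0.05, 0.021 and 0.016; the calls of HLA-C (0.21), GAPDH (-0.33), BCL2L1 (-0.29) and RPS2 (-0.38) held at other sizes. With 1 library left out, the gene AMD1 ranged from -0.065 to 0.043, and list medians ranged from -0.012 to 0.16 for cytokines, -0.13 to 0.075 for mesenchymal, -0.092 to 0.00071 for end joining, -0.044 to 0.0092 for polyamine, -0.051 to 0.018 for ribosomal protein, -0.024 to 0.059 for luminal, -0.091 to 0.012 for mitosis, -0.16 to 0.0069 for histone, -0.047 to 0.052 for NF-kB and -0.047 to 0.059 for immediate early genes. The cause was not tested. Because TPM carries no depth, counting error could not be separated from other variation.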

Other observations

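The test of short genes, that of leukocyte RNA in all libraries and that of irradiated replicates 2 and 3, the placing of GARS1 and SARS1 among the synthetases and the comparison of gene types were chosen after the values they bear on were seen; the other tests were written before.

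Outside the fixed lists, some cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, fell. ATF4 itself fell from 401 ± 8.77 to 305 ± 2.23 TPM (log2 change -0.39 ± 0.03 SE, adjusted p = 0.00309). Of 12 cytosolic synthetases known as ATF4 targets, 7 fell and none rose, with a median log2 change of -0.28; MARS1 went from 200.01 to 139 TPM (-0.53), GARS1 from 216 to 154 TPM (-0.49), CARS1 from 58.7 to 43.0 TPM (-0.44) and YARS1 from 84.6 to 64.0 TPM (-0.40). None of 8 other cytosolic synthetases passed (median -0.02), nor did any of 17 mitochondrial synthetases (median 0.04). The hypothesis that a lower ATF4 programme accounts for this predicts a lower median in the targets than in the other cytosolic enzymes. The difference of medians was -0.26 (exact one-sided permutation of the 20 genes, p = 0.000445), and -0.20 among the 18 genes whose values had not been seen (p = 0.0008). Genes are not independent replicates, the target set was taken from general knowledge, and the activity of ATF4 was not measured, so this may reflect any shared regulator of these genes.

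The falls of the DNA replication and ribosome biogenesis lists, not called with an estimated correlation (adjusted p = 0.229 and 0.224), may have technical sources, which were tested first. A bias of GC content and length is argued against. After cubic trends on both were removed from each library, the medians moved from -0.23 and -0.24 to -0.28 and -0.31, further from 0. The same correction changed the whole count to 2281 calls, 835 higher and 1446 lower. Both medians lay more than 2 standard errors below 0, but these errors were taken over list members as if independent. With estimated correlations of 0.17 and 0.23 among members, they may be too small. A larger TPM share of a few abundant transcripts is also argued against, since the medians were -0.25 and -0.26 with mitochondrially encoded genes removed and median-ratio scaling. Nor did abundant genes fall to this extent in general: 0% of 10000 random lists matched on mean expression had medians as low, the lowest being -0.16 and -0.18. A difference of day, batch or culture time between the groups stays open. The labels give no day or batch, and no culture time for the controls. The biological explanation the design names, irradiation, stays open too.

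The rise of interferon-stimulated and antigen presentation genes, whose lists were not called with an estimated correlation (adjusted p = 0.404 and 0.224), together with IL32 and CD68 could come from leukocyte RNA. Over all irradiated libraries the summed TPM of 7 abundant leukocyte transcripts rose by 13.8 with a standard error of 13.3, which decides nothing because PTPRC alone, at 40.4 TPM in irradiated replicate 1, accounts for nearly all of the change; TYROBP was at 0 in all 6 libraries and CD3E at 0.05 TPM or less. In irradiated replicates 2 and 3, where IL32 was at 36.0 and 33.1 TPM, the sum exceeded the control mean of 0.76 TPM by at most 0.73 TPM. This was below 10% of the rise of IL32 (2.91 TPM over all libraries), so these 7 transcripts argue against leukocytes there. The leukocyte marker CD3D, not among the 7, was at 2.09 and 2.16 TPM there and at 0.24 to 1 TPM in the controls. Leukocyte RNA in these 2 libraries is therefore not excluded. GC content and length (median 0.18 after correction) and a uniform shift of the TPM scale (median 0.18 above that of all genes) are argued against as well. The standard errors behind this were taken over list members as if independent. Across genes, the log2 change was lower at higher mean expression (r = -0.18). No lists matched on expression were drawn for this rise, so a shift that depends on level was not tested. Irradiated replicate 1 also had the highest TPM share of assembled loci (0.736%, against 0.365% to 0.405% in the others). What gives PTPRC its value there is not known. Irradiation, an unlabelled batch and a difference in culture time remain open for the rest.

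Short RNA genes were over-represented among the large changes: 12 of 12 called genes with transcripts under 300 bases changed at least 2-fold, against 40 of 1514 longer called genes (Fisher's exact test, two-sided p = 6.47e-19). Imprecise TPM of short genes is a candidate source, since their median residual SD was 4.80 times that of longer genes at the same level, so that only large changes can pass. The Fisher test counts called genes only, so this imprecision partly fixes its outcome. Of all tested genes, 12 of 157 short ones were called, against 1514 of 14087 longer ones. No biological explanation was tested for the short genes, of which SNORA12 and BCYRN1 passed in every alternative that tested them.

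Among called long non-coding genes (lincRNA and antisense), 69 were higher and 14 lower, against 845 and 551 protein-coding genes (Fisher's exact test, two-sided p = 2.14e-05). The counts were 64 and 19 against 707 and 736 after median-ratio scaling, and 65 and 29 against 728 and 1372 after GC and length correction. Within 5 bins of mean expression no such difference was seen: the odds ratio fell from 3.21 to 1.11 (exact p = 0.873), and was 0.99 (p = 1) and 1.35 (p = 0.269) in those 2 alternatives.

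The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1550 genes, 65 of them at least 2-fold, and was the 1 split with the highest count in both; the highest other split gave 2 and 2. For the lists, 2 splits reached 7, the real one and 1 other, whose value was also 7. Every other split mixes irradiated with control libraries on each side. This puts much of the real difference into the spread within sides, so low gene counts there are no independent support. It also leaves part of that difference between the sides, so the list counts are not a chance rate.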
